A study of Homo sapiens with 2 samples.

How the data were processed

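RNA sequencing compared 2 libraries from PC9 cells, an established human lung adenocarcinoma line that carries an activating EGFR deletion. One library came from the control line and the other from the line expressing TAZ4SA, an active mutant of the transcriptional co-activator TAZ (gene symbol WWTR1) in which serines phosphorylated by the LATS kinases are replaced by alanine. Per the labels' protocols, the cells were transduced with lentiviral Tet-On vectors, TAZ4SA was induced with 50 ng/mL doxycycline for 24 h, and RNA was extracted with a column kit. The protocol text is shared by both samples and does not say separately whether the control received doxycycline or carried an empty construct vector. How RNA was selected for the libraries and whether they kept strand are not given in the sources used here.

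The submitters' processing notes name Trim Galore, STAR, HTSeq, DESeq2 and the GRCh37 build, without versions, roles or settings. The deposited table holds, for 16642 genes with Ensembl identifiers and symbols, a normalized count (a signal value) for each of the 2 libraries and a log2 fold change. These deposited signal values are read counts that the authors divided by a single factor per library: every value of a column was a whole multiple of that column's step, within a tolerance of 0.01 reads, for 100% of values in both columns. The steps gave size factors of 0.689 for the TAZ4SA library and 1.11 for the control. Multiplying by these factors recovered 29668388 reads for TAZ4SA and 47684754 for the control. The geometric mean of the 2 factors was 0.875, whereas median-of-ratios factors of these 2 columns alone have a geometric mean of 1; what else entered the authors' scaling is not given in the sources used here. The ratio of the 2 factors, which alone sets the fold changes, was 1.61 and the ratio of the depths was also 1.61. The authors' deposited log2 fold change equalled the log2 ratio of the columns to within 0.000136 for the 16584 genes above 0 in both libraries. The table holds 0 columns of p-values. The rule by which genes entered it is not given in the sources used here; 264 genes had under 10 reads over both libraries.

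Because the table holds normalized values, the log2 ratio reported for each gene was computed from log2(normalized count + 1), TAZ4SA over control, which understates differences of low genes; folds are ratios of the normalized counts without the pseudocount. TMM-scaled CPM, first planned, was run as an alternative. Each ratio has an exact (Clopper-Pearson, conditional binomial) 95% interval computed from the recovered reads. It covers counting error only, and reads are not independent molecules. With 1 library per group, no test of the conditions can be made, no p-value is reported, and the spread between cultures is unknown. A gene was counted as at least 2-fold higher or lower if its mean normalized count was at least 20, its log2 ratio reached 1 in size and its interval excluded a ratio of 1.

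A total of 34 gene lists (657 genes, of which 592 are in the table and 560 had a mean normalized count of at least 20) were fixed before the data were examined, as were the named genes rule and the thresholds. For the 31 lists with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Members 1.5-fold higher or lower were counted where the interval excluded a ratio of 1. An interval given for a list median is an order-statistic 95% interval over its genes, which are not independent. The named genes were WWTR1, the 10 highest and 10 lowest log2 ratios among genes with a mean normalized count of at least 100, up to 4 members per list with the largest absolute log2 ratio, and CYR61, CTGF, ANKRD1, AXL and ABL2 whatever their values. The values of 1 gene that the rule names are not reported here. Alternatives covered scaling (TMM, upper quartile, total counts, DESeq2 median of ratios), pseudocounts of 0.1, 0.5 and 5, filters, fold thresholds, bins and summary statistics.

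The procedure was tested on simulated Poisson counts for this comparison with 200 changed genes. It called 98% of the 50 genes made 3-fold higher, 100% of the 50 made 3-fold lower and 100% of those changed 8-fold in either direction. It also called 29 of 13862 unchanged genes, and 95.6% of the counting intervals held the true ratio. The simulation contained no variation between cultures. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 (the last 2 for scaling factors only). The annotation at hand was GENCODE 29 on GRCh38, which is not the build of the table, so no coordinates are printed; it was used by gene identifier for transcript length and GC content. Near-identical paralogs (the AKR1C genes, RN7SL1 and RN7SL2, HSPA1A and HSPA1B, KRT6A and KRT6B) and overlapping antisense genes are uncertain, since the handling of shared reads and strand is not given in the sources used here.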

Results

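The transcriptome of PC9 cells expressing the active mutant TAZ4SA was compared with that of control PC9 cells by RNA sequencing, with 1 library per group. The recovered depth was 29668388 reads for the TAZ4SA library and 47684754 for the control. Of the 16642 genes in the table, 14074 had a mean normalized count of at least 20. The libraries were close overall: the median log2 ratio was 0.00019, 89.9% of these genes lay within 1.5-fold, and the correlation of log2 normalized counts across genes, which are not independent replicates, was 0.986. Values below are single measurements without replicates; each bracketed range is a 95% interval of counting error, and differences describe these 2 libraries rather than a tested effect of TAZ4SA.

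The expressed gene itself was examined first. WWTR1 (ENSG00000018408), which encodes TAZ, had a normalized count of 15628 in the TAZ4SA library and 4933 in the control, a 3.17-fold difference (3.07 to 3.27). The table does not separate construct reads from reads of the endogenous gene. The antisense gene WWTR1-AS1, named here outside the preset rule, had 22 reads against 9, and reads of overlapping genes cannot be separated without strand. These reads are not scaled for depth, which was 1.61 times greater in the control, so the scaled difference is larger.

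The next question was which genes differed with TAZ4SA. At the 2-fold threshold, 267 genes (1.9% of those measured) were higher and 219 (1.56%) were lower in the TAZ4SA library. At 4-fold the numbers were 60 higher and 28 lower. In the authors' deposited table, 276 genes with a mean normalized count of at least 20 had a log2 fold change of at least 1 and 227 of at most -1; over all genes of that table the numbers were 637 and 596. The counts depended on the filter: with a mean normalized count of at least 100, 113 genes were at least 2-fold higher and 87 lower.

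Among the genes with a mean normalized count of at least 100, the highest ratio was that of OLR1, the receptor for oxidized LDL, at 7325 normalized counts against 134, or 54.6-fold (46.4 to 64.7). It was followed by MFAP5, a microfibril protein, at 43.0-fold (19.3 to 119) on only 6 control reads, TMEM52B at 27.1-fold (14.8 to 55.3) and AGPAT4, an acyltransferase of phospholipid synthesis, at 16.2-fold (10.6 to 25.8). The kinase gene NUAK2 was 12.7-fold higher, the transcription factor gene EGR1 10.3-fold, ANKRD1 9.51-fold and the metalloprotease gene ADAMTS6 8.46-fold. RN7SL2 and RN7SL1, near-identical genes for the RNA of the signal recognition particle, were 7.97-fold and 7.79-fold higher. Among the lowest ratios at the same minimum, PALMD was 9.27-fold lower (6.51 to 13.6), with 47.9 normalized counts against 444. ADCY5, an adenylyl cyclase gene, was 4.97-fold lower, and KRT13, a keratin of stratified epithelium, was 4.46-fold lower at 2495 against 11119. RN7SK, a small nuclear RNA that restrains transcription elongation, was also 4.46-fold lower. RN7SK, RN7SL1 and RN7SL2 lack a poly(A) tail, and how RNA was selected for the libraries is not given, so their ratios may reflect library preparation. UBL4B was 4.30-fold lower, IL1RAPL2 4.27-fold and RARRES1 3.99-fold. The aldo-keto reductase gene AKR1B10 was 3.84-fold lower (3.71 to 3.97), the aldehyde dehydrogenase gene ALDH3A1 3.83-fold, and CASP14, a caspase of keratinocyte differentiation, 3.78-fold.

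**Figure D1:**
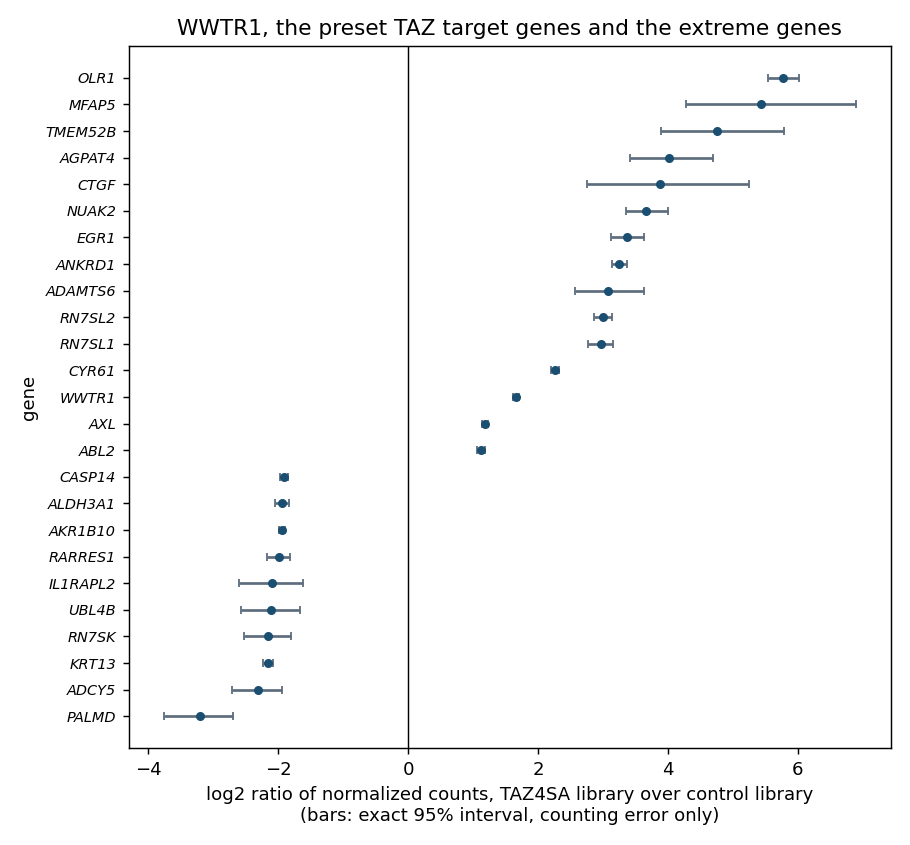
Log2 ratio of normalized counts (TAZ4SA library over control library, horizontal axis) for WWTR1, the preset genes CYR61, CTGF, ANKRD1, AXL and ABL2, and the 10 highest and 10 lowest genes with a mean normalized count of at least 100. Bars are exact 95% intervals of counting error. ABL2 is not a member of the YAP/TAZ target list. Among those plotted, OLR1 lies at the top and PALMD at the bottom; CTGF and MFAP5 have wide intervals because the control library held 7 and 6 of their reads.

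Genes known as targets of TAZ and its paralog YAP were higher as a group. Of 20 measured members, 12 were at least 1.5-fold higher and 0 were lower by that much; 19 had a log2 ratio above 0. The median log2 ratio was 1.03 (0.46 to 1.40 over the genes), above all 10000 random lists. CTGF (ENSG00000118523), a secreted matricellular protein gene, was 14.7-fold higher (6.76 to 38.1) but at a low level, 92.8 normalized counts against 6.30. The related CYR61 (ENSG00000142871) was abundant and 4.80-fold higher (4.62 to 5.001). ANKRD1 (ENSG00000148677) stood at 6443 against 678 normalized counts. The remaining 8 of the 20 were within 1.5-fold, and 6 of the 22 genes of the list also belong to another list.

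Several components of the Hippo pathway, which restrains YAP and TAZ, were higher too. Among 27 measured members, 7 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.23 (0.04 to 0.48), above all random lists. LATS2, a kinase that phosphorylates TAZ, was 2.75-fold higher, AMOTL2 2.19-fold, the scaffold gene SAV1 1.91-fold and the phosphatase gene PTPN14 1.76-fold. LATS2, AMOTL2 and PTPN14 are also members of the target list, and without them the median of the Hippo list was 0.13. The Hippo list also holds YAP1 itself and genes of the TEAD and VGLL families. YAP1, named here outside the preset rule, had a log2 ratio of -0.17 (-0.20 to -0.13).

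Receptor tyrosine kinases, the ABL kinases, the ligand genes GAS6 and PROS1 and the adhesion molecule gene L1CAM formed a list of 16 measured genes, of which 6 were at least 1.5-fold higher and 0 lower (median log2 ratio 0.27, 0.03 to 1.06, above all random lists). The receptor kinase gene AXL (ENSG00000167601) was 2.27-fold higher (2.19 to 2.35), at 10793 against 4748 normalized counts. ABL2 (ENSG00000143322), a non-receptor tyrosine kinase gene, was 2.17-fold higher (2.08 to 2.27), at 7421 against 3415. The ligand genes GAS6 and PROS1 were 2.49-fold and 6.45-fold higher, PROS1 on 28 and 7 reads. The other members at least 1.5-fold higher were L1CAM and the receptor gene FGFR1, named here outside the preset rule. Of 7 measured EGF family ligands, 1 was at least 1.5-fold lower and 0 were higher. That gene was EGF, 2.46-fold lower at 39.2 against 96.3 normalized counts, and TGFA was 1.49-fold higher; BTC and NRG2 had intervals that included a ratio of 1. The list median of -0.14 lay at percentile 14.0 of random lists.

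Feedback genes of MAPK signalling had a median log2 ratio of -0.19 (-0.32 to 0.11), at percentile 0.03, but only DUSP6, an ERK phosphatase gene, was at least 1.5-fold lower (2.36-fold) among 16, and EGR1 was higher. The sprouty genes SPRY1 and SPRY4 were 1.33-fold and 1.32-fold lower, while FOSL1 and CCND1, named here outside the preset rule, were 1.32-fold and 1.30-fold higher. Of the 16, 11 had log2 ratios below 0 and 5 above. With a 10% trimmed mean in place of the median, the list lay at percentile 4.51, within the central range. Immediate-early genes went both ways, with 4 of 15 at least 1.5-fold higher and 1 lower and a median of 0.06 (percentile 83.8, or 99.89 with the trimmed mean): the transcription factor gene ATF3 was 4.45-fold higher and FOSB 1.65-fold, while FOS was 1.72-fold lower.

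Mesenchymal genes, 9 of which were measured, had 4 members higher and 1 lower by 1.5-fold, with a median log2 ratio of 0.53 (-0.01 to 1.02; percentile 99.97). FN1, encoding fibronectin, was 5.45-fold higher (5.30 to 5.60) at 30623 against 5622 normalized counts, the transcription factor gene SNAI2 2.04-fold and TAGLN 2.04-fold, whereas S100A4 was 2.52-fold lower. Of 18 epithelial genes, 17 were within 1.5-fold, the median was 0.05 (percentile 77.9), and KRT18 was 1.38-fold higher while CLDN4 was 1.31-fold and CLDN3 1.80-fold lower. Among 30 matrix and adhesion genes, 4 were higher and 3 lower by 1.5-fold. Their median was 0.18 (-0.09 to 0.25), above all random lists. THBS1, encoding thrombospondin, was 2.92-fold higher, the collagen gene COL5A1 2.60-fold and MMP9 4.10-fold on few reads (28 and 11), and the integrin gene ITGB3 was 1.86-fold lower. Actin cytoskeleton genes differed by small amounts in one direction, with 19 of 21 above 0, a median of 0.16 (percentile 99.98) and TPM1, a tropomyosin gene, highest at 1.56-fold.

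**Figure D2:**
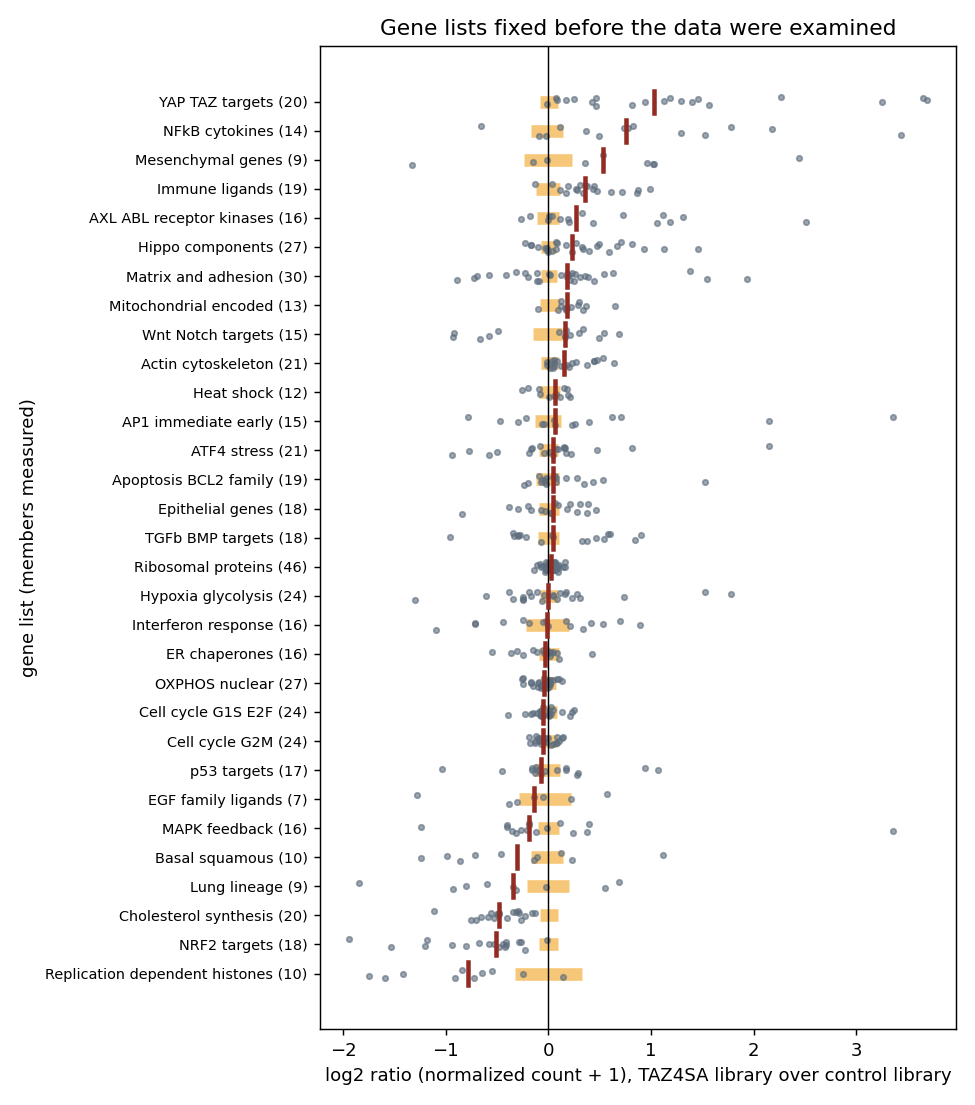
Log2 ratios (TAZ4SA library over control library, horizontal axis) of the measured members of each gene list (grey points), the list median (red bar) and the central 95% of medians of 10000 random lists matched on expression (orange band). The YAP/TAZ target list has the highest median, 1.03, and the replication-dependent histone list the lowest, -0.78.

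Genes of NF-kB signalling and cytokines were higher in the TAZ4SA library. Of 14 measured, 8 were at least 1.5-fold higher and 1 lower, with a median log2 ratio of 0.76 (0.11 to 1.53), above all random lists. The adhesion molecule gene ICAM1 was 4.53-fold higher (4.25 to 4.85), the NF-kB subunit gene RELB 3.45-fold and the apoptosis inhibitor gene BIRC3 2.89-fold. The cytokine gene IL6 was 11.7-fold higher (6.36 to 23.5) at a low level, 126 against 10.8 normalized counts. Antigen presentation and immune ligand genes were higher by smaller amounts: 18 of 19 were above 0, 5 by at least 1.5-fold, with a median of 0.35 (0.27 to 0.47; above all random lists). HLA-B was 1.99-fold higher, the NKG2D ligand gene ULBP2 1.85-fold, the peptide transporter gene TAP1 1.82-fold and CD274, encoding PD-L1, 1.65-fold. In the interferon response list, of 16 measured, 2 were higher and 2 lower by 1.5-fold, the median was -0.01 (percentile 47.1), and MX1 was 2.17-fold and OAS1 1.64-fold lower while IFI6 was 1.91-fold higher.

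In 2 metabolic lists every measured member was lower in the TAZ4SA library. All 18 NRF2 target genes, which serve antioxidant and detoxifying functions, had log2 ratios below 0, and 7 were at least 1.5-fold lower. Their median was -0.51 (-0.80 to -0.42), below all 10000 random lists. AKR1B10 was lowest, and AKR1C1, AKR1C2 and AKR1C3, close paralogs that can share reads, were 2.90-fold, 2.30-fold and 2.27-fold lower. All 20 measured genes of cholesterol synthesis and its regulation were also below 0, with a median of -0.48 (-0.53 to -0.31), below all random lists; 5 were at least 1.5-fold lower. Among the mevalonate pathway genes, MVK was 1.69-fold lower, HMGCS1 1.63-fold and MVD 1.58-fold.

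Lineage markers were lower on balance, with members going both ways. Of 9 lung lineage genes measured, 3 were at least 1.5-fold lower and 1 higher (median -0.34, -0.81 to -0.03, percentile 0.32). The pioneer factor gene FOXA1 was 1.90-fold lower and the surfactant gene SFTPB 3.72-fold lower on 15 and 90 reads. The measured members above 0 were CAV1, 1.61-fold higher, and AGER, 1.47-fold higher (1.12 to 1.93) and named here outside the preset rule. HNF4A had an interval that included a ratio of 1. Of the 22 genes of the list, 12 are in the deposited table. With a minimum mean of 100, only 6 members remained and the list lay at percentile 3.99. Of 10 basal and squamous genes, 4 were lower and 1 higher by 1.5-fold (median -0.30, -0.86 to 0.12, percentile 0.15). KRT5 was 2.37-fold, KRT6A 1.99-fold and KRT15 1.81-fold lower, and TP63 was 2.21-fold higher on 37 and 27 reads. Markers of other cell types were few at this level, with 2 of 10 fibroblast, 1 of 12 leukocyte and 3 of 10 endothelial markers measured. COL6A3 was 1.96-fold lower and COL1A1 1.19-fold higher, and ITGAM was 2.46-fold higher on 32 and 21 reads. The 3 endothelial markers were not near the floor. ESAM was 1.23-fold lower (869 against 1069 normalized counts) and CDH5 1.17-fold lower (1362 against 1589). The interval of EGFL7 (725 against 662) included a ratio of 1.

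Proliferation and housekeeping genes differed little between the libraries. All 24 G1/S and all 24 G2/M genes lay within 1.5-fold, with medians of -0.05 (percentile 7.31) and -0.05 (percentile 5.1). The largest differences were those of E2F2, 1.31-fold lower, and CCNB2, 1.14-fold lower. All 46 ribosomal protein genes lay within 1.5-fold with a median of 0.03 (percentile 66.7), RPS7 being highest at 1.12-fold.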

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

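TMM scaling of the recovered reads with the pseudocount of 1, thinning of control reads, removal of shared or AKR1 genes, and GC and length correction were chosen after seeing the data. TMM-scaled CPM with a prior count of 2 was the measure first planned and became an alternative once the table proved to hold normalized counts; the others were planned as alternatives. The ratio of WWTR1 kept its direction and stayed within its counting interval under all 8 alternatives run for it, and the log2 ratios of the named genes stayed within their counting intervals under every scaling and pseudocount. The 4 scalings shifted the median of all genes by at most 0.0043. The numbers of genes at least 2-fold higher (267) and lower (219) moved by over 1.5 times with the filter and threshold, by construction: 418 and 341 without a filter, 113 and 87 with a mean of at least 100, 586 and 625 at 1.5-fold, 60 and 28 at 4-fold, and 129 and 73 where the interval bound itself had to reach 2-fold. The 418 alternative values for the 31 gene list medians lay within the intervals of those medians. Medians near 0 that lay within the central range of random lists changed sign under some alternatives. Among the lists outside that range, 1 value reversed: the 10% trimmed mean of the Wnt and Notch list was -0.013 (percentile 45.8), and that list lay at percentile 96.1 with control reads thinned to the TAZ4SA total. With the trimmed mean, MAPK feedback genes lay at percentile 4.51, immediate-early genes at 99.89 and TGF-beta and BMP genes at 98.6; lung lineage genes lay at 3.99 with a mean of at least 100. The cause was not tested in these 5 lists. An adjusted p of the authors could not be varied because the table holds 0 such columns, and edgeR or DESeq2 tests, replicate removal and blocks were not run, with 1 library per group. No paired analysis was possible because each group has 1 library. Depth limits low genes most: a gene with 7 control reads, such as CTGF, has an interval from 6.76-fold to 38.1-fold.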

Other observations

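The tests of GC content and length, of the AKR1 paralogs, of S phase and of RNAs without a poly(A) tail, and the grouping of genes by symbol, were added after the list medians had been seen.

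Further preset gene groups described other aspects of the cells. Replication-dependent histone genes had the lowest list median, -0.78 (-1.42 to -0.55), below all 10000 random lists, with 7 of 10 measured members at least 1.5-fold lower. HIST1H1E was 3.48-fold lower, HIST1H2BC 3.17-fold, HIST1H2BD 2.71-fold and HIST2H2BE 1.91-fold, all on few reads (9 to 131 per library). Mitochondrially encoded mRNAs were slightly higher, 12 of 13 above 0 with a median of 0.18 (percentile 99.94). The largest ratios were those of MT-ND6 (1.57-fold), MT-ND4L (1.29-fold), MT-ND1 (1.27-fold) and MT-ND4 (1.23-fold). All 27 nuclear genes of oxidative phosphorylation were within 1.5-fold, with a median of -0.05 (percentile 9.56) and UQCRC1 lowest at 1.20-fold. Wnt and Notch genes had a median of 0.16 (percentile 99.14), yet 3 of 15 were lower and 1 higher by 1.5-fold: TCF7 was 1.90-fold, HEY1 1.90-fold and NOTCH3 1.59-fold lower, and the Wnt antagonist gene DKK1 1.61-fold higher. The list mixes members that went opposite ways. The Notch genes HES1 and JAG1, named here outside the preset rule, had log2 ratios of -0.58 and -0.49, while NRARP, NOTCH1 and NOTCH2 were above 0. Of the measured Wnt genes only TCF7 was below 0, though several of the others had intervals that included a ratio of 1. The median and the trimmed mean of that list differ in sign.

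The remaining lists had medians inside the central range of random lists. TGF-beta and BMP genes had a median of 0.04 (percentile 77.4, or 98.6 with a 10% trimmed mean), with 4 of 18 higher and 1 lower; BMP4 was 1.88-fold, INHBA 1.79-fold and TGFB1 1.52-fold higher, and ID1 was 1.95-fold lower. For p53 targets the median was -0.07 (percentile 14.995), with CDKN1A 1.92-fold and BTG2 2.13-fold higher and GDF15 2.05-fold lower. ATF4 stress genes had a median of 0.05 (percentile 84.7), with the amino acid transporter gene SLC7A5 1.75-fold higher and SLC7A11 and CEBPB 1.92-fold and 1.71-fold lower. Hypoxia and glycolysis genes had a median of -0.002 (percentile 37.3), with the glucose transporter gene SLC2A3 3.42-fold and ADM 2.89-fold higher and CA9 2.47-fold lower. In the BCL2 family and caspase inhibitor list the median was 0.05 (percentile 81.6), and BIRC3 alone reached 1.5-fold; PMAIP1 was 1.45-fold higher. Endoplasmic reticulum chaperones (median -0.03, percentile 16.1) and heat shock genes (median 0.06, percentile 82.5) had 0 members beyond 1.5-fold, HSPA5 being 1.35-fold higher and EDEM1 1.46-fold lower. Of the 31 lists, 10 medians lay above and 6 below the central 95% of random lists. About 1.55 would lie there if the genes of a list varied independently. Genes of a list can vary together between any cultures, and some lists share members, so the excess is a description and not a test.

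Genes sharing a symbol stem gave 208 families with at least 8 measured members. The medians of 27 lay outside the central 95% of matched random lists, against 10.4 if the genes of a family varied independently, which they may not. The lowest were HIST (16 genes, median -0.88), AKR (9 genes, median -0.60) and ALDH, the aldehyde dehydrogenases (16 genes, median -0.33, 14 of them below 0). HIST and AKR share genes with the replication-dependent histone and NRF2 target lists, so they are not separate observations. The highest were FZD, the frizzled receptors (8 genes, median 0.31), and ADAMTS (8 genes, median 0.28). Genes with the stem KRT lay on the high side, with a median of 0.17 over 28 genes (percentile 99.84, 18 above 0 and 10 below). The stem does not separate keratin genes from their pseudogenes. Among the keratins of the preset lists and the extreme genes, KRT8 (1.30-fold) and KRT18 (1.38-fold) were higher, whereas KRT13, KRT5, KRT6A, KRT6B, KRT15, KRT16 and KRT19 were lower.

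The higher YAP/TAZ target median was set against sequence bias. GC content and transcript length explained 0.358% of the variance of log2 ratios (limited to a size of 1), and with both regressed out the list median was 1.04 (0.44 to 1.41), against 1.03 before, which argues against that bias as its source. A difference between the lines unrelated to TAZ4SA, such as separate passage, selection or doxycycline exposure, stays open because each group has 1 library. An effect of TAZ4SA stays open for the same reason and was not tested.

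The lower NRF2 target and cholesterol synthesis medians could reflect sequence bias or, for NRF2 targets, reads shared between paralogs. After GC and length were regressed out, the medians were -0.53 (-0.80 to -0.41) and -0.48 (-0.52 to -0.32). These values argue against sequence bias. Without the AKR1 genes the NRF2 median was -0.43 (-0.58 to -0.28), so the lower median did not rest on those genes alone. That prediction was written after the list medians had been seen, when all 18 members already lay below 0. It therefore does not test read sharing. Culture differences between the 2 lines, such as density or medium at harvest, were not tested and stay open, as does an effect of TAZ4SA.

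The lower histone median was weighed against 3 explanations. It was -0.78 (-1.41 to -0.57) after GC and length were regressed out, which argues against that bias. Fewer cells in S phase would lower the G1/S genes, whose median was -0.052 (-0.08 to 0.01, percentile 7.31), with all 24 within 1.5-fold. That prediction was written after the list medians had been seen. How far a moderate fall in S phase would lower these genes is unknown, so it cannot be excluded. Less carry-over of RNAs without a poly(A) tail cannot be told apart from other sources: 15 small nuclear and nucleolar RNAs, RMRP and RPPH1 among them, had a median of 0.13 (-0.35 to 0.57) at a median of only 31.8 normalized counts, RN7SK and RMRP (2.46-fold) were lower, and RN7SL1 and RN7SL2 were higher. A library preparation difference that acts unevenly on such RNAs may contribute.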
